A study of Homo sapiens with 4 samples.

How the data were processed

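The series holds 4 RNA sequencing libraries, 1 control and 1 HES1-depleted library from each of 2 established lymphoma cell lines. Per the labels' protocols, cells were grown in RPMI medium with fetal bovine serum, HES1 was depleted with an siRNA, RNA was purified on columns with DNase, and libraries were made with a stranded mRNA kit. What the control cells received is not given in the sources used here. The submitters' processing notes name bcl2fastq, FastQC, Bowtie2 2.2.9, HTSeq 0.9.0, DESeq2 1.14.1, R 3.4.0 and the build GRCh37, without giving the role of each tool or whether counting used the strand. Overlapping genes, near-identical families such as histones and ribosomal protein pseudogenes, and antisense genes such as ZNFX1-AS1 are therefore less certain than others.

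Per the file headers, the authors deposited raw read counts per RefSeq transcript and, in a second table, the counts of 1 transcript for each of 22257 genes. The second table was used here. It also holds log2 values made by the authors: for 95.9% to 97.4% of genes with 10 or more reads these lay within 0.01 of quantile-normalized log2(count + 1) recomputed here. Its signed fold columns, deposited by the authors for each line, equal 2 raised to the difference of these log2 values, or minus the inverse where that is below 1. For 367 genes the first table marks another transcript as best, and those counts served as an alternative. No other column of values per sample was present in the gene table (0 columns).

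Library totals in the gene table ran from 14881715 to 19619543 reads, and the 10 most abundant genes held 4.06% to 6.70% of them. Counts were scaled by TMM (factors 0.983 to 1.02) and log2 ratios were formed with a prior count of 2. A gene was counted in a line when its higher library had at least 100 reads and its ratio was at least 2-fold, a log2 ratio of 1. With 1 library per group there is no p-value within a line, and 95% intervals of a ratio come from the exact binomial distribution of its reads, which covers counting error only. Reads carried no molecular identifiers as far as the sources used here state.

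For the change common to both lines, edgeR 4.0.16 was run in R 4.3.3 with line and treatment as terms. It used the quasi-likelihood test, filterByExpr and Benjamini-Hochberg adjustment. The model leaves 1 residual degree of freedom and treats the 2 lines as replicates. Its p-values rest mostly on a spread between these lines that is shared across genes. They do not measure how closely the lines agree for a given gene. GTSF1, with log2 ratios of -1.26 and -1.34, had an SE of 0.56, and FTL, with -0.84 and -3.57, one of 0.65. DESeq2 1.42.0 and limma 3.58.1 were alternatives. The 31 gene lists were fixed before the data were examined and scored in a line over members with at least 10 reads summed over its libraries. Medians were ranked among 10000 random lists drawn from 10 bins of mean expression. camera and fry (limma) tested 28 lists in the common model.

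The rule for named genes was also fixed before the data were examined: HES1 first, then in each line the 10 genes highest and 10 lowest in log2 ratio, the 12 higher and 12 lower genes with the largest smaller-of-2 ratio common to both lines, and up to 4 members of each list with the largest mean ratio. Genes without a clear symbol may be passed over in the text. BHLHE40, HEY1, MYC, ALK, STAT3, GZMB, JAKMIP1, LYZ, CD14 and FCN1, and the genes called only with the offset, were chosen after their values were seen.

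GC content and length came from GENCODE transcripts of GRCh38 matched by RefSeq accession, for 94.2% of the 22257 genes and 96.1% of those with 100 reads in both lines. This annotation is of another build than the submitters', so it was used for transcript GC, length and current symbols only, and no coordinates are given. In each line a spline surface with 4 degrees of freedom for GC and for log2 length, fitted to genes with at least 100 reads, was subtracted from the log2 ratios, or entered in edgeR as an offset. This step was chosen after seeing the data. It removes any real difference that follows GC or length as well.

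edgeR, edgeR with the offset and the subtraction of the trend were tested on simulated counts with 200 changed genes; the list percentiles, camera, fry and the overlap counts were not. At a dispersion of 0.01 edgeR recovered 100 of 100 genes at a log2 fold change of 1 and 100 of 100 at 2, with 14 false calls among 13519 genes. At a dispersion of 0.14, close to the 0.138 estimated here, it recovered 0 of 100 and 23 of 100 with 2 false calls among 13420. Its unchanged genes had an SD of SUDHL1 log2 ratios of 0.80, against 0.42 in the data over genes with at least 100 reads there. That simulation held no GC and length trend, so it matches the dispersion estimate but not the spread within SUDHL1. With the offset and a dispersion of 0.05, close to the 0.0498 estimated here with the offset, it recovered 32 of 100 and 99 of 100 with 6 false calls among 12778. In that simulation the trend put in had the same form as the one fitted, and each changed gene changed equally in both lines. Its false calls therefore say nothing about calls in the data that rest on a single line. For the subtraction, the trend fitted to these data was put on counts with Poisson noise and 200 changed genes. Over the 8596 unchanged genes the correlation of the lines was -0.83 before and 0.03 after subtraction. The same form of surface was put in and taken out, so this shows only that the subtraction removes such a trend. The data, with a correlation of -0.41 before subtraction, differ from that simulation.

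Alternatives tried were other scalings, read minimums, prior counts and thresholds, no filter and no line term in edgeR, other test tools, other list members and set tests, and, added after seeing the data, the GC and length adjustment, the best-marked transcripts, the authors' log2 values and the HES and HEY list without HES1. Mitochondrially encoded genes, 1 of the 31 lists, had no member in the table (0 of 13). B-cell markers (1 and 2 measured members) and erythroid markers (2 and 2) were too few to describe.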

Results

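Transcript levels were measured by stranded mRNA sequencing in 2 established human T-cell lymphoma lines that express the ALK tyrosine kinase, named SUDHL1 and SUP-M2 in the labels. HES1 is a basic helix-loop-helix transcriptional repressor that acts downstream of NOTCH receptors, and the series asked which transcripts differ when it is depleted from these cells. Each line contributed 1 control library and 1 HES1-depleted library, so the 4 groups held 1 library each and no difference within a line had a replicate check. The gene table held 16812411 reads for the SUDHL1 control, 19273767 for HES1-depleted SUDHL1, 14881715 for the SUP-M2 control and 19619543 for HES1-depleted SUP-M2. Intervals below are 95% and cover counting error only. Log2 ratios are HES1-depleted over control, and levels are TMM-scaled CPM.

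HES1 itself (NM_005524) was lower in the HES1-depleted library of both lines. In SUDHL1 it had 510 reads in the control and 210 in the depleted library, or 30.4 and 10.9 CPM, a log2 ratio of -1.47 (-1.72 to -1.25). In SUP-M2 it had 498 and 278 reads, or 34.1 and 13.9 CPM, a log2 ratio of -1.28 (-1.51 to -1.08). Both intervals excluded 0, and the direction in the 4 libraries follows their labels for this gene. The intervals leave out differences between libraries, and in SUP-M2 1356 of 9929 genes were at least 2-fold lower. Of its relatives, the repressor BHLHE40 had log2 ratios of 0.30 in SUDHL1 and -1.07 in SUP-M2, and HEY1, with 53 and 64 reads in SUDHL1 and 85 and 63 in SUP-M2, had 0.07 and -0.86. Others were lower in SUDHL1: BHLHE41 had 22 and 7 reads there (-1.58, -3.32 to -0.58) and HEY2 34 and 17 (-1.10, -2.13 to -0.32). In SUP-M2 HEY2 had 32 and 57 reads (0.37). Of the measured HES and HEY family members, HES1 included, 3 of 9 in SUDHL1 and 3 of 6 in SUP-M2 were at least 2-fold lower.

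**Figure D1:**
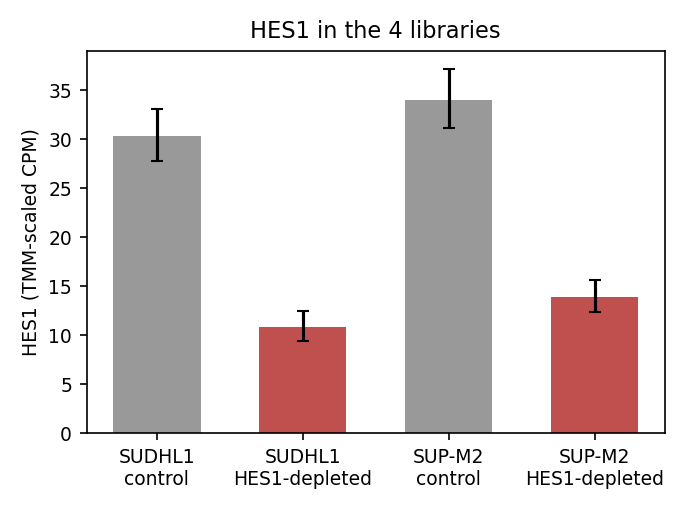
HES1 level in CPM (TMM-scaled) in the 4 libraries, 1 library per bar, with 95% Poisson intervals for counting error. The depleted libraries lie at 10.9 and 13.9, below the controls at 30.4 and 34.1.

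The libraries also differed along the GC content and length of the transcripts. Over the 8796 genes with at least 100 reads in the higher library of both lines and an annotated transcript, the log2 ratio was higher at high GC in SUDHL1 (Spearman's rho across genes 0.56) and lower at high GC in SUP-M2 (rho -0.71). Medians ran from -0.19 below the first quartile of GC to 0.35 above the last in SUDHL1, and from 0.73 to -0.89 in SUP-M2. The ratio followed transcript length more weakly in SUDHL1 (rho -0.14) than in SUP-M2 (rho 0.43). GC and length together accounted for 28.2% of the variance of the ratio in SUDHL1 and 59.9% in SUP-M2. Relative to the SUDHL1 control, levels in the SUP-M2 control followed GC (rho 0.56) and those in HES1-depleted SUP-M2 did not (rho 0.03). Relative to HES1-depleted SUDHL1, the rho was 0.41 for the SUP-M2 control and -0.23 for HES1-depleted SUP-M2. Values with this trend subtracted, called GC-adjusted below, were added after seeing the data and stand beside each gene group.

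**Figure D2:**
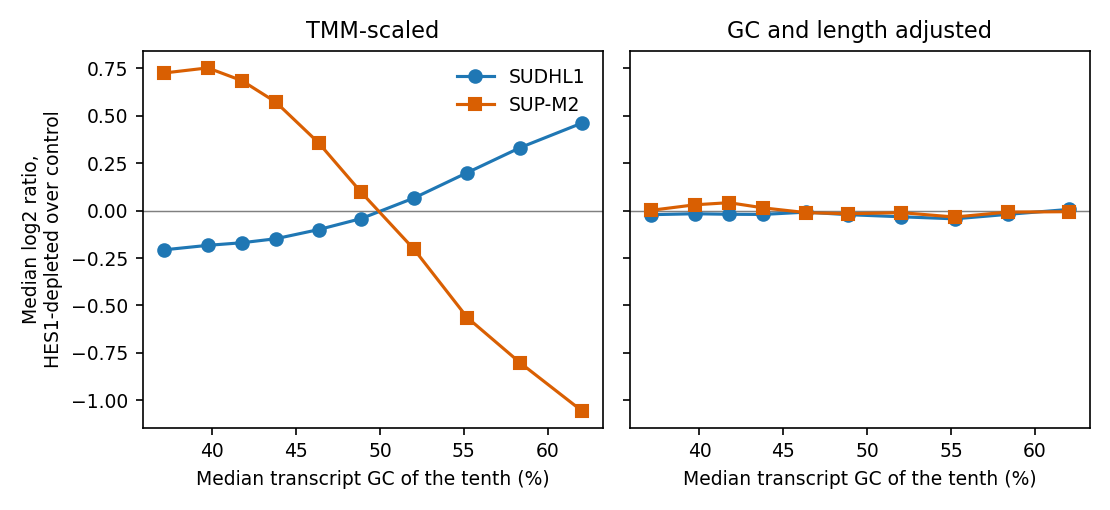
Median log2 ratio (HES1-depleted over control) of genes in 10 bins of transcript GC, for SUDHL1 and SUP-M2, as TMM-scaled ratios and after subtraction of the GC and length trend of each line. In the lowest and highest bins the TMM-scaled medians are -0.21 and 0.46 in SUDHL1 and 0.73 and -1.05 in SUP-M2.

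In SUDHL1, the genes highest in the HES1-depleted library relative to the control had varied functions. TNC, which encodes the matrix protein tenascin C, had 783 reads in the control and 6251 in the depleted library (log2 ratio 2.79, 2.69 to 2.91). CXCR5, a chemokine receptor of follicular helper T cells and B cells, had 15 and 272 reads (3.82, 3.23 to 4.84), and CYP4F11, a cytochrome P450, had 5 and 112 (3.85, 3.02 to 5.94). SPN (the sialophorin CD43), S100A8 (a calcium-binding protein of neutrophils and monocytes), TIE1 (an endothelial receptor), CUX2 and C20orf123 (current symbol OCSTAMP) had log2 ratios of 3.45, 3.36, 3.16, 3.09 and 3.06. CD82, a tetraspanin, had 43 and 399 reads (2.96). PTPRJ, a receptor tyrosine phosphatase, was lowest relative to its control, with 7722 and 1612 reads (-2.46, -2.54 to -2.38). The transcription factor ZNF395 had 2591 and 833 reads (-1.84), and C9orf72, RELN, STC1, DIP2C, ARHGEF10, ARRDC3 and PLAC8 had log2 ratios between -1.79 and -1.57. Among 10099 genes with at least 100 reads in the higher library, 202 were at least 2-fold higher and 49 at least 2-fold lower. On the 9695 genes with an annotated transcript these counts were 197 and 48, and 92 and 54 after GC adjustment. The authors' quantile-normalized values gave 157 and 92, so the share of higher genes was 80.5% with TMM scaling, 63.1% with those values and 63.0% after GC adjustment.

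In SUP-M2 many more transcripts differed. FTL, the ferritin light chain, had 139692 reads in the control and 16109 in the depleted library (log2 ratio -3.57, -3.59 to -3.54). DDIT4, a stress-induced inhibitor of mTORC1, had 20904 and 3379 reads (-3.08), and the metallothionein MT2A had 144 and 19 (-3.23, -4.15 to -2.68). UBA7 (the ISG15-activating enzyme), IDH2 (mitochondrial isocitrate dehydrogenase), B3GALT4, C10orf10 (DEPP1), C7orf68 (HILPDA, a lipid droplet protein), RGS1 and H1FX (a linker histone) had log2 ratios of -3.02, -2.79, -2.72, -2.72, -2.64, -2.57 and -2.53. On the higher side ITGA4, the alpha4 integrin, had 438 reads in the control and 3468 in the depleted library (2.53, 2.39 to 2.68). COLEC12, CERKL, SLC4A4, DISC1, DIO2, RASAL2, CPS1 and MBNL3 had log2 ratios between 2.46 and 2.86. Among 9929 genes, 1479 were at least 2-fold higher and 1356 at least 2-fold lower. On the 9531 genes with an annotated transcript these were 1431 and 1303, and 368 and 389 after GC adjustment. GC-adjusted values were -2.65 for FTL, -2.22 for DDIT4, -1.89 for MT2A and 1.81 for ITGA4.

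Gene lists fixed before the data were examined were described by the median log2 ratio of their measured members and its percentile among 10000 random lists of the same size and expression. Of the 28 lists with 3 or more measured members, 10 lay above the middle 95% of random lists and 2 below it in SUDHL1, and 5 above and 14 below it in SUP-M2. After GC adjustment these were 4 and 6 in SUDHL1 and 3 and 5 in SUP-M2. The 4 include the cytotoxic granule list, for which the adjustment is void. The PI3K list lay at the lower edge in SUP-M2, at percentile 2.73 in the draw of random lists behind these counts and 2.44 in the draw behind the percentiles below, where 6 lists were under the range.

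Hypoxia and glycolysis genes were lower in HES1-depleted SUP-M2, where 12 of 30 measured members were at least 2-fold lower and 1 at least 2-fold higher, with a median of -0.79 (percentile 0.01). NDRG1 (-2.51), PFKFB4 (-2.29), the carbonic anhydrase CA9 (-2.25) and ANKRD37 (-1.12) were examples. In SUDHL1 the list median was 0.11 (percentile 98.8), NDRG1 was at 0.87 and ANKRD37, with 3025 and 1438 reads, at -1.27. After GC adjustment the medians were -0.61 in SUP-M2 and -0.18 in SUDHL1 (percentiles 0 and 0.29). Genes for ATF4 signalling and ER stress had medians of -0.06 in SUDHL1 and -0.47 in SUP-M2, or -0.23 and -0.16 after adjustment, and PPP1R15A had log2 ratios of -0.48 and -2.21. The ATF4 list was below the random range in SUP-M2 only before adjustment (percentile 1.73) and in SUDHL1 only after it (percentile 0.01). The heat shock list was above the random range in both lines, with medians of 0.26 and 0.75, and after adjustment, with medians of 0.13 and 0.45, in SUP-M2 only (percentiles 96.4 and 99.7). HSPA8, the constitutive Hsp70, had 15171 and 35227 reads in SUDHL1 and 23440 and 118164 in SUP-M2, whereas HSPA6, a stress-inducible Hsp70, had 93 and 6 reads in SUP-M2.

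MYC targets and G2/M genes were above the random range in SUP-M2. In SUDHL1 MYC targets were inside it and G2/M genes below it (percentile 0.03). MYC targets, mainly nucleolar and translation genes, had a median of -0.04 in SUDHL1 and 0.59 in SUP-M2 (percentiles 50.3 and 98.9). POLR1B (2.06), NCL (1.87), WDR43 (1.86) and HSPD1 (1.79) were examples in SUP-M2. After GC adjustment 12 of 29 members were at least 2-fold higher there and the median was 0.90. In SUDHL1 the adjusted median was -0.14, below the random range (percentile 1.52). MYC itself was at -0.03 and -0.23. The G2/M list had medians of -0.27 and 0.75, with HMMR at -0.41 and 2.37. Its adjusted medians were -0.17, below the random range (percentile 0.53), and 0.18, inside it (percentile 96.8). S-phase and DNA replication genes had medians of -0.09 and 0.42, inside the random range (percentiles 28 and 90.6), and adjusted medians of -0.16 and 0.47, outside it (percentiles 0.615 and 100). Cytosolic ribosomal protein genes went the other way in SUP-M2, with 15 of 41 at least 2-fold lower and a median of -0.84, against 0.08 in SUDHL1. After adjustment 6 of 39 were at least 2-fold lower in SUP-M2. The adjusted SUP-M2 median of -0.24 was inside the random range (percentile 4.19), against -0.02 in SUDHL1. Nuclear genes of oxidative phosphorylation had medians of 0.03 and -0.54 and adjusted medians of 0.03 and -0.18, the latter inside the random range (percentile 13.9). Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, had medians of 0.14 and -1.48, with HIST1H2BK at -1.79 in SUP-M2, and adjusted medians of -0.02 and -0.42.

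NF-kB, cytokine, cytotoxic granule and monocyte lists were above the random range in SUDHL1 and below it in SUP-M2. Immediate early genes had medians of 0.17, inside that range (percentile 96.1), and -1.07, with 17 of 31 members at least 2-fold lower in SUP-M2. The phosphatase DUSP1 was at 1.51 and -2.14 and the zinc finger factor EGR2 at 1.06 and -2.03. NF-kB pathway genes and targets had medians of 0.34 and -0.93, with TRAF2 at 0.69 and -1.54. Adjusted SUP-M2 medians were -0.67 for the immediate early list and -0.50 for the NF-kB list (percentile 0 for both). The SUDHL1 ones were -0.09 and -0.07, inside the random range (percentiles 10.7 and 24.3). Cytokines, chemokines and their receptors had medians of 0.51 and -0.69. After adjustment these were 0.24, still above the random range (percentile 99.0), and -0.23, inside it (percentile 6.56). Over members of at least 100 reads the unadjusted SUP-M2 median was -0.35, inside the random range (percentile 9.39). CCL3 had 8 and 70 reads in SUDHL1 (2.67), and IL8 (CXCL8) had 32 and 4 reads there (-2.66, -5.16 to -1.71). Cytotoxic granule genes had medians of 0.47 and -1.25. GZMA had 3098 and 7582 reads in SUDHL1 and PRF1, perforin, 2643 and 4529, while GZMB was at 0.32 and -1.25. GC adjustment was void for that list because it had values for only 7 of 10 and 6 of 9 members. The monocyte and macrophage list had medians of 1.21 (percentile 100) and -0.93 (percentile 1.51). S100A9 (1.81 and -2.14) and the scavenger receptor CD163 (3149 and 8369 reads in SUDHL1) were among its 7 measured members in SUDHL1, where the adjusted median was 1.27. In SUP-M2 the adjusted median was -0.35, inside the random range (percentile 10.1). Before adjustment 3 of 6 measured members were at least 2-fold lower there and 1 at least 2-fold higher, and S100A8 held only 7 and 3 reads. Interferon response genes had medians of 0.07 and 0.38, the latter above the random range (percentile 99.2), with 8 of 31 members at least 2-fold higher and 6 at least 2-fold lower in SUP-M2. ISG20 was at -2.93 there, IFI44L had 0 and 62 reads (4.83), and the adjusted medians were -0.00 and 0.03. With members of at least 100 reads the SUP-M2 interferon median was 0.10 (percentile 74.9).

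Genes of the NOTCH pathway, in which HES1 acts, stood inside the random range in both lines. They had medians of 0.08 (percentile 79.9) and -0.30 (percentile 18.9), with 2 of 23 members at least 2-fold higher and 3 at least 2-fold lower in SUP-M2 and none in SUDHL1. After GC adjustment the medians were 0.01 and -0.01 and none of 22 measured members was 2-fold away from the control in either line. HES and HEY family genes had medians of 0.07 and -0.97, or 0.18 and -0.86 without HES1 itself, and the corepressors of HES1 0.06 and -0.96, with the corepressor TLE2 at 14 and 38 reads in SUDHL1 and 69 and 31 in SUP-M2. With members of at least 100 reads the SUP-M2 corepressor median was -0.41, inside the random range (percentile 9.53). Adjusted medians were -0.21 and -0.63 for the family and -0.12 and -0.25 for the corepressors. STAT3 and ALK-lymphoma genes had medians of 0.12 and -0.48 and adjusted medians of -0.04 and 0.10. TIMP1 (1.26 and -2.08) and SERPINA1 (1.05 and -1.60) differed most there, and ALK was at 0.09 and 0.28 and STAT3 at -0.06 and -0.11. T-cell receptor and identity genes had medians of -0.17 and -0.28 and adjusted medians of -0.16 and -0.31. Genes of PI3K signalling with IL7R had medians of 0.09 and 0.16, and the adjusted SUP-M2 median had the other sign (0.05 and -0.26). CDK inhibitors and G1 regulators had medians of 0.03 and -0.47 (adjusted -0.02 and -0.20), and BCL2 family and caspase genes 0.06 and -0.43 (adjusted 0.06 and -0.26). The p53 targets had medians of -0.22 and -0.23 (adjusted -0.19 and -0.19). In SUDHL1 that list was below the random range before and after adjustment (percentiles 0.35 and 0.16). In SUP-M2 it was inside the range (percentiles 8.3 and 6.25). CDKN1A was at 0.35 and -1.49 and the BH3-only gene BMF at 1.13 and -1.56. Cholesterol synthesis genes had medians of 0.41 and -0.72 and adjusted medians of 0.21 and -0.14, with TM7SF2 at 0.88 and -1.18. Their SUDHL1 median was above the random range before and after adjustment (percentiles 99.99 and 99.91). Their SUP-M2 median was below it before adjustment (percentile 0.07) and inside it after (percentile 15.5). RNA interference genes had medians of 0.06 and 0.78 and adjusted medians of 0.06 and 0.20, with DICER1 at 0.34 and 1.73. With members of at least 100 reads the SUP-M2 median was 0.66 (percentile 93.5).

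**Figure D3:**
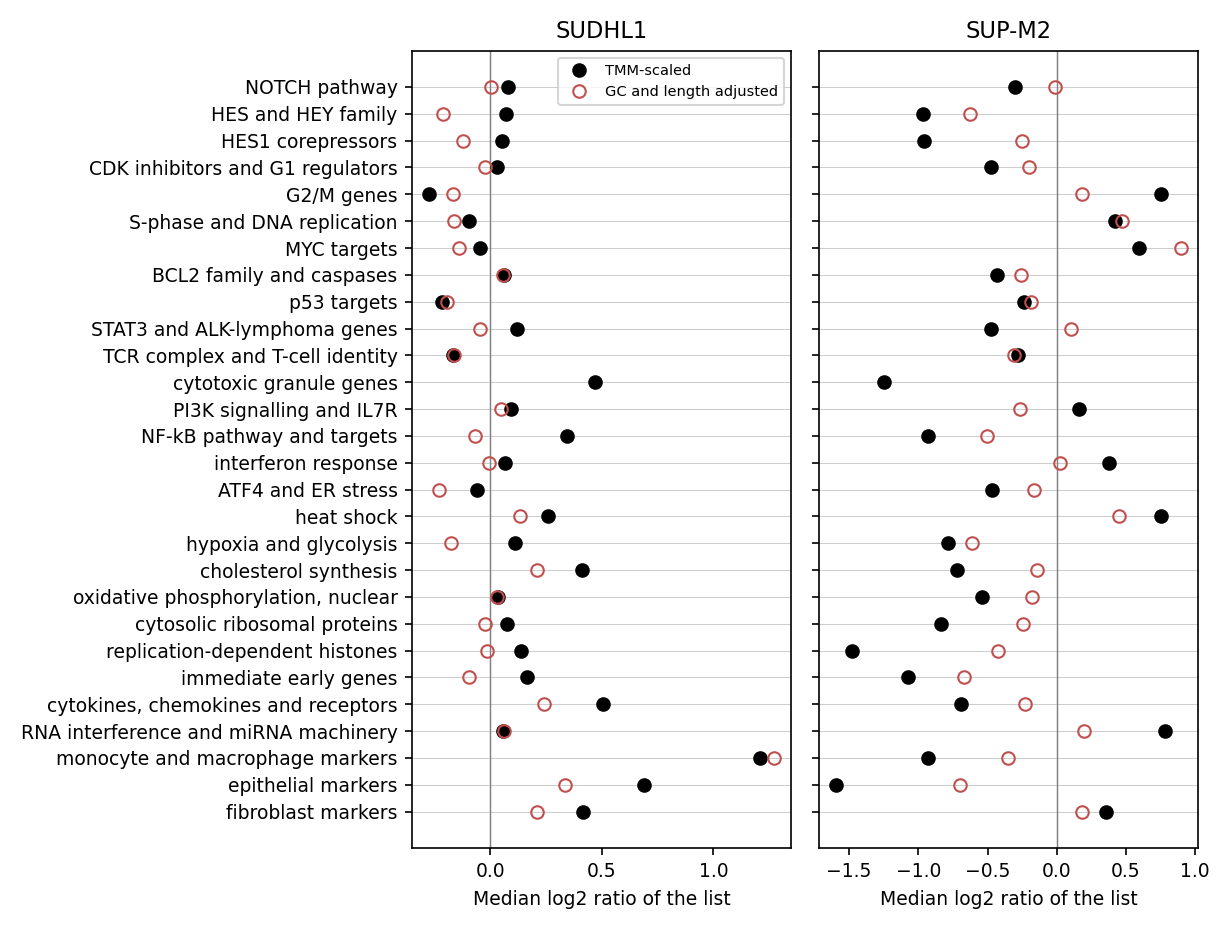
Median log2 ratio (HES1-depleted over control) of the measured members of each list with at least 4 of them in both lines, as TMM-scaled ratios (filled) and after GC and length adjustment (open; not drawn for cytotoxic granule genes, where it is void), for SUDHL1 and SUP-M2. The monocyte list lies at 1.21 and -0.93 and the histone list at 0.14 and -1.48 in the 2 lines.

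Genes that differed in the same direction in both lines were few. Among 9152 genes with at least 100 reads in the higher library of each line, 9 were at least 2-fold lower in both, against 4.04 for independent lists, and 8 at least 2-fold higher in both, against 17.9. The 9 were HES1, ZNF395 (-1.84 in SUDHL1 and -1.43 in SUP-M2), the antiproliferative gene BTG1 (-1.36 and -1.65), C7orf68 (-1.34 and -2.64), GTSF1 (-1.26 and -1.34), the mRNA decay factor ZFP36 (-1.26 and -1.52), the MYC antagonist MXI1 (-1.47 and -1.24), DDIT4 (-1.19 and -3.08) and ANKRD37 (-1.27 and -1.12). LOC154761, ZNFX1-AS1 (ZFAS1) and C6orf48 followed, just short of 2-fold in SUDHL1, and ZNFX1-AS1 in SUP-M2 too (-0.96 and -0.98). The GC-adjusted ratios of ZNFX1-AS1 were -1.25 in SUDHL1 and -0.08 in SUP-M2. The 8 higher ones were TNC (2.79 and 1.12), CD226 (2.68 and 1.17), EHF (1.96 and 1.27), PSD3 (1.49 and 1.75), TWF1 (1.26 and 1.31), TXNIP (1.10 and 1.33), TMEM2 (CEMIP2; 1.10 and 1.60) and HSPA8 (1.01 and 1.88). SLFN5, CLVS1, SORL1 and SPTBN1 were next, with SPTBN1 at 0.93 and 2.41. After GC adjustment 10 genes were at least 2-fold lower in both lines, against 1.40 for independent lists, and 4 at least 2-fold higher, against 1.44. Of the first 9, 7 were among those 10, and the 4 were TNC, HSPA8, CLVS1 and JAKMIP1.

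With the 2 lines as replicates and the line as a covariate, edgeR's quasi-likelihood test called no gene among 13414 at an adjusted p of 0.05. It gave 104 genes at an unadjusted p under 0.05, while DESeq2 called 0 genes with 99 unadjusted and limma-voom called 1, FTL, with an adjusted p of 0.0454 and 218 unadjusted. HES1 had an edgeR log2 fold change of -1.40 (SE 0.66, unadjusted p = 0.0334, adjusted p = 1), lower in 2 of 2 lines. DDIT4 had the smallest unadjusted p, 0.00037, at a log2 fold change of -2.15 (SE 0.60). When the GC and length trend entered edgeR as an offset, an alternative added after seeing the data, 26 genes were called higher and 24 lower among 12728, with 629 at an unadjusted p under 0.05. HES1 then had an adjusted p of 0.017, C7orf68 and TNC 5.14e-05, and DDIT4, BTG1 and MXI1 0.000248. Of these 50 genes, 18 had fewer than 20 reads in one of the lines, so their call rests on the other line, and 11 of the 26 and 21 of the 24 had at least 20 reads in each line and adjusted ratios of one sign.

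In the set test common to both lines, camera with a preset correlation of 0.01 called 8 of 28 lists lower and 4 higher at an adjusted p of 0.05. The lower lists were replication-dependent histones (4.27e-07), hypoxia and glycolysis (1.6e-05), immediate early genes (2.69e-05), ribosomal proteins (5.97e-05), NF-kB (0.0138), oxidative phosphorylation (0.0178), ATF4 and ER stress (0.0355) and the HES and HEY family (0.0449). The last list holds HES1, the depleted gene, and without it, an alternative added after seeing the data, its adjusted p was 0.337. The higher lists were MYC targets, RNA interference and fibroblast markers (0.0178 each) and heat shock (0.038). TMM-scaled SUDHL1 medians did not all share these directions. Of the lists called lower, histones (0.14), hypoxia (0.11), ribosomal proteins (0.08) and NF-kB (0.34) were above the random range there. Immediate early genes (0.17), oxidative phosphorylation (0.03) and the HES and HEY family (0.07) had positive medians, and ATF4 and ER stress a negative one (-0.06). Of the lists called higher, MYC targets had -0.04 in SUDHL1, and the others had positive medians in both lines. No list was called with an estimated correlation, with an adjusted p = 0.793 or more for each, nor by fry, which asks whether a list's genes move one way on balance (smallest adjusted p = 0.565). No single member passed edgeR's test over all genes, and 1 gene of the ATF4 list, DDIT4, did when adjusted over the list alone. On GC-adjusted values camera's preset test gave 2.41e-05 for hypoxia, 0.000189 for immediate early genes and 0.000571 for MYC targets. Of the 12 lists above, 8 kept an adjusted p under 0.05, and the HES and HEY family (0.185), oxidative phosphorylation (0.154), RNA interference (0.209) and fibroblast markers (0.154) did not. The p53 list was called there only (0.031), and no list with an estimated correlation (adjusted p = 0.837 or more).

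The log2 ratios of the lines ran against each other. Across the 9152 genes Pearson's r was -0.41 and Spearman's rho -0.43, and 31.6% of genes had the same sign; genes are not independent replicates. In all, 69 genes were at least 2-fold higher in SUDHL1 and 2-fold lower in SUP-M2, against 14.6 for independent lists. Among them were S100A9, the integrin ITGAX (1.55 and -1.62), DUSP1 and the potassium channel KCNN4 (1.60 and -1.47). The reverse pattern was found for 2 genes, RELN among them, against 4.97 for independent lists. After GC adjustment r was -0.03 and rho -0.05, 47.2% of genes had the same sign, and the opposite groups held 6 genes and 1 gene, against 1.52 and 1.33; the 1 gene was RELN (-1.73 and 1.44).

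**Figure D4:**
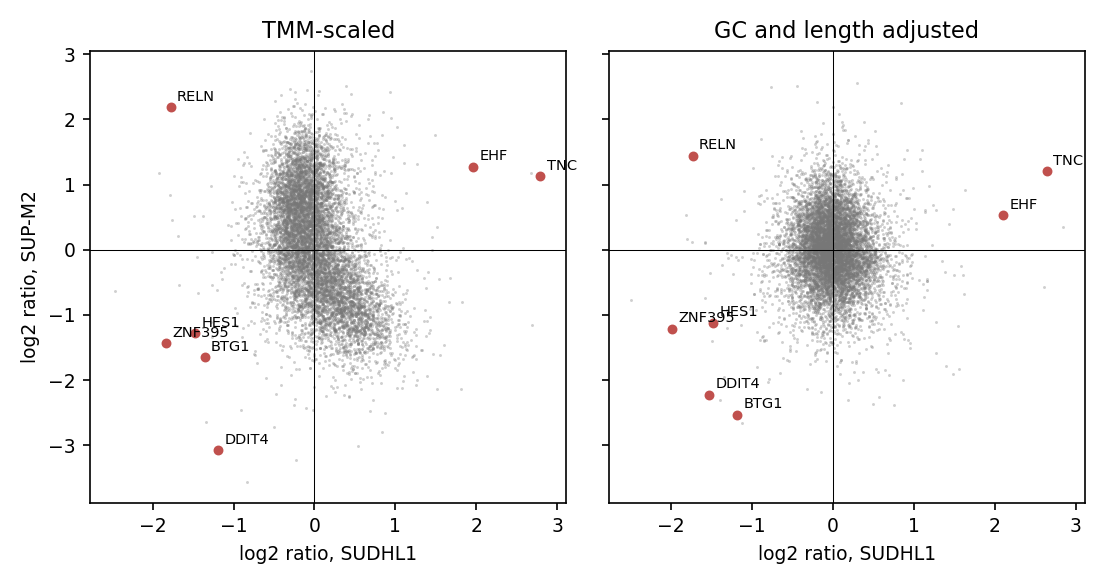
Log2 ratios (HES1-depleted over control) of SUDHL1 against SUP-M2 for genes with at least 100 reads in the higher library of each line, TMM-scaled and GC and length adjusted, with 7 named genes marked. The correlation across genes is -0.41 and -0.03.

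The authors' deposited table gave signed folds of -3.00 for HES1 in SUDHL1 and -2.41 in SUP-M2. In the authors' deposited table, SUDHL1 had 1069 genes at a fold of 2 or above and 1268 at -2 or below, and SUP-M2 had 3090 and 3214, with no read minimum. With the minimum of 100 reads these were 157 and 92, and 1372 and 1335.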

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

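All tests of explanations in this part were chosen after the results were seen, except the one within ribosomal protein genes. The results of the next paragraph were picked out because the libraries of the 2 lines differed in opposite directions. With 1 library per group the difference was not tested for any of them.

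Gene counts ran opposite in the lines: 69 genes were at least 2-fold higher in SUDHL1 and lower in SUP-M2, and 2 the reverse. Among those 2 was RELN, at -1.78 in SUDHL1 and 2.19 in SUP-M2. List medians outside the random range on opposite sides were -0.27 and 0.75 for G2/M genes in SUDHL1 and SUP-M2, 0.12 and -0.48 for STAT3 and ALK-lymphoma genes, 0.47 and -1.25 for cytotoxic granule genes, and 0.34 and -0.93 for NF-kB. The other such pairs were 0.11 and -0.79 for hypoxia and glycolysis, 0.41 and -0.72 for cholesterol synthesis, 0.0758 and -0.84 for ribosomal proteins, 0.14 and -1.48 for histones, 0.51 and -0.69 for cytokines, and 1.21 and -0.93 for monocyte markers.

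A technical candidate explanation for the opposite shifts is a difference in GC and length representation between libraries. Subtracting that trend took the correlation of the lines from -0.41 to -0.0275. Within the 39 ribosomal protein genes, which share a function and usually move together, the SUP-M2 ratio fell with GC (rho -0.70), and in SUDHL1 the rho was 0.69. The trend was thus present among genes that share a function too. The trend argues poorly as the whole source of the SUP-M2 differences: of 2734 genes at 2-fold or more, 445 stayed there in the same direction after it was subtracted, and 757 genes in all were at 2-fold or more then, 312 of them newly or in the other direction. Whether those 757 follow HES1 depletion or another difference between single libraries stays open, and no biological explanation could be separated by a replicate.

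The 9 genes at least 2-fold lower in both lines were weighed next. The fitted GC and length trend does not account for 7 of them, HES1 included, which stayed at least 2-fold lower in both lines after its subtraction. In all, 10 genes were then lower in both lines, against 1.40 for independent lists. The subtraction itself brought in ARRDC3 (-0.55 to -1.40 in SUP-M2), IQCG (-0.67 to -1.20 in SUP-M2) and FTL (-0.84 to -1.12 in SUDHL1). The count of 10 thus rests partly on the adjustment. For ANKRD37 and ZFP36 the trend is not excluded as the source, since their SUP-M2 ratios went from -1.12 to -0.35 and from -1.52 to -0.74. DDIT4, MXI1, C7orf68 (HILPDA) and BTG1 are known to respond to hypoxia or nutrient stress. Of the fixed hypoxia list, 29 members had at least 100 reads in both lines. Before adjustment 1 of them, ANKRD37, was lower in both lines, against 0.0285 at the share of all 9152 genes. After adjustment 0 were, against 0.0317, an expectation too low for 0 to count against hypoxia. CA9, with 35 and 20 reads in SUDHL1, had adjusted ratios of -1.33 and -1.24. A culture difference in oxygen or cell density between control and depleted cells, apart from HES1, and an effect of HES1 depletion cannot be told apart, because each allows the adjusted hypoxia medians of -0.18 in SUDHL1 and -0.61 in SUP-M2 and each group is 1 library. The SUDHL1 median was 0.11 before adjustment (percentile 98.8), so its negative sign rests on the adjustment.

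The monocyte markers higher in HES1-depleted SUDHL1 kept an adjusted median of 1.27, so the fitted GC and length trend does not account for their median. Monocytes or macrophages among the depleted cells would bring abundant LYZ, CD14 and FCN1 transcripts, which held 2 reads together in the depleted library and 1 in the control, while S100A9 had 1461 and CD163 8369. A hypothesis left open is that the lymphoma cells themselves express more of these genes when HES1 is low; with 1 library per group a difference between cultures may give the same values, and the adjusted median of 1.27 does not separate them.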

How the results depend on the processing

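Alternatives marked as added were chosen after seeing the data: the GC and length adjustment, the best-marked transcripts, the authors' quantile-normalized log2 values and the HES and HEY list without HES1. The HES1 ratio stayed within its counting interval under all 6 alternatives run for each line, from -1.58 to -1.47 in SUDHL1 and from -1.29 to -1.12 in SUP-M2. DESeq2 size factors, total counts, a prior count of 0.5 and the best-marked transcripts left the counts of 2-fold genes within 1.5 times. Another read minimum or threshold changes the totals by construction. With at least 10 reads SUDHL1 had 582 higher and 218 lower genes. With at least 1000 reads SUDHL1 had 50 and 20, and SUP-M2 984 and 434. At a log2 ratio threshold of 1.5 they were 46 and 11, and 434 and 344. The split by direction is not fixed in that way. In SUP-M2 the share of higher genes was 47.0% at 10 reads, 52.2% at 100 and 69.4% at 1000. In SUDHL1 it was 72.75%, 80.5% and 71.4%. At 1000 reads the correlation of the lines was -0.30, with 4 genes higher in both and opposite groups of 12 and 0. The authors' values gave 92 lower genes in SUDHL1, a correlation of -0.36 and 9 genes lower in SUDHL1 and higher in SUP-M2; the cause was not tested. The GC and length adjustment gave 92 higher genes in SUDHL1, 368 higher and 389 lower in SUP-M2, a correlation of -0.0275, 4 genes higher in both lines and opposite groups of 6 and 1. Lists outside the random range were then 4 above and 6 below in SUDHL1 and 3 above and 5 below in SUP-M2, which also had 3 above when members needed 100 reads. Of list medians outside the random range, and of named genes at 2-fold or more, that adjustment reversed the sign of the SUDHL1 medians of the STAT3 and ALK-lymphoma (-0.0445), NF-kB (-0.0661), hypoxia (-0.18), ribosomal protein (-0.0245) and histone (-0.0150) lists, the SUP-M2 median of the STAT3 list (0.10), and in SUP-M2 BAD (0.17) and BCL3 (0.10). The same holds for ADRM1 (0.28), CCS (0.09), RINL (0.05) and MAP2K2 (0.00) in SUP-M2, which are among the 69 opposite genes. Signs also turned for medians inside that range, among them PI3K in SUP-M2 (-0.26) and immediate early genes in SUDHL1 (-0.09). In the common test the offset called 26 higher and 24 lower genes and limma-voom 1 lower, while the other 5 alternatives called 0; the cause of the limma-voom call was not tested. camera with an estimated correlation and fry called 0 lists higher and 0 lower, and on adjusted values camera called 2 higher. Without HES1 in its list, camera called 7 lists lower. No paired analysis was possible beyond the line term because the labels give no replicate numbers, and no library can be left out: without the SUP-M2 control, SUP-M2 has no ratio and the common test no residual degree of freedom. With 1 library per group, depth limits genes of few reads, and missing replicates and the GC and length trend limit the others.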

Other observations

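The tests with the GC and length offset and the genes named here were chosen after seeing the data. With the offset in edgeR, genes called higher across both lines included TNC (log2 fold change 1.91, SE 0.33, adjusted p = 5.14e-05), SPTBN1 (1.54, adjusted p = 0.00224), MYOF (1.21, adjusted p = 0.04) and EHF (1.38, adjusted p = 0.0246), each higher in 2 of 2 lines. SPP1, the secreted phosphoprotein osteopontin, had 94 and 518 reads in SUDHL1 but 3 and 16 in SUP-M2 (adjusted p = 0.000833), and ENPP1, with 369 and 1907 reads in SUDHL1, had 1 and 7 in SUP-M2. Beside the genes already named, FTL (-1.90, adjusted p = 0.00224), ARRDC3 (-1.46, adjusted p = 0.00215), PTPRJ (-1.65, adjusted p = 0.00148), CCNG2 (-1.24, adjusted p = 0.0377), JUN (-1.16, adjusted p = 0.04), STC1 (-1.49, adjusted p = 0.0414), ANGPTL4 (-1.67, adjusted p = 0.0425) and CA9 (-1.31, adjusted p = 0.043) were called lower, each in 2 of 2 lines. Without the offset none of these had an adjusted p under 0.05 in edgeR.

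Some calls of that fit rest on a single line. RGS1 had 425 and 96 reads in SUP-M2 and 0 and 1 in SUDHL1, ITGA4 had 438 and 3468 against 0 and 1, and CXCR5 had no reads in either SUP-M2 library (0 and 0).

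After GC and length adjustment, 7 genes were at least 2-fold higher in one line and lower in the other: S100A9 (1.55 in SUDHL1 and -1.16 in SUP-M2), ITGAX (1.28 and -1.10), DUSP1 (1.27 and -1.58), EMP1 (1.49 and -1.91), PHLDA1 (1.56 and -1.83), C4orf34 (1.40 and -1.78) and RELN (-1.73 and 1.44). Of these, C4orf34 passed 2-fold in both lines only after adjustment, with -0.89 in SUP-M2 before it. The lines also differ in their own repertoire: SUDHL1 control had 3098 GZMA reads and SUP-M2 control 1, whereas CA9 had 35 and 3271. Epithelial markers had medians of 0.69 and -1.59 over 5 and 4 measured members (adjusted 0.34 and -0.70), and fibroblast markers 0.42 and 0.35 over 4 and 6 (adjusted 0.21 and 0.18), among them the collagen gene COL6A3 with 21298 and 42247 reads in SUDHL1 and 640 and 2539 in SUP-M2.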
